A study of Homo sapiens with 8 samples.

How the data were processed

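RNA was measured in 8 cultures of established human breast cancer cell lines. MCF-7 is a luminal line that carries the estrogen receptor, and MDA-MB-231 is a triple-negative line with mesenchymal features. Each line was studied as the parental culture and as a radioresistant derivative, named MCF-7RR and MDA-MB-231RR. Per the labels' protocols, the derivatives had received 15 fractions of 2 Gy with recovery in between, RNA was taken 4 to 10 passages after the last irradiation, and parental cultures were handled alike without irradiation. Each of the 4 groups has 2 arrays, which the labels call biological replicates. The labels do not say whether the 2 arrays of a derivative come from separate selections, so p-values measure the spread between these cultures and not between independently derived resistant lines.

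Per the labels' protocols, 6 ug of total RNA per sample was turned into biotin-labelled cRNA and hybridised to whole-transcript Affymetrix arrays. Per the submitters' processing notes, the scans were processed with Affymetrix Expression Console. The version, the summarisation algorithm, the background step and the genome build are not given in the sources used here. The deposited table holds 1 value per probe set for 33297 probe sets and 8 arrays, and its values were read as log2 expression because they span 1.90 to 14.6. The log base is thus inferred from the values. The array medians run from 6.25 to 6.49 and the 95th percentiles from 10.33 to 10.45. No detection calls were used, so dim probe sets cannot be told from absent transcripts. Changes that start or end near the bottom of the range understate the fold. The number of arrays limits the precision.

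Probe sets were named through the platform annotation, with symbols updated through their gene number against the RefSeq gene table of GRCh38.p14 for 19429 of the 19460 probe sets that carry 1 symbol. A further 1754 probe sets carry several symbols and 12083 are unnamed here, and none of these was given a gene name. Where several probe sets share a symbol (769 genes), the one with the highest mean over the 8 arrays was used, which left 18417 genes. A gene was tested when its highest group mean was above 4.67, the 25th percentile of all deposited values. This left 16097 genes and removed 2320. No coordinates are given, because the build behind the deposited table is not given in the sources used here. RefSeq was used only for names, gene classes, gene lengths and the order of neighbouring genes.

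All values were tested on the log2 scale, as deposited, with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes). A group-means model was fitted to all 8 arrays, so that the 4 groups share 1 estimate of the spread (4 residual and 8.06 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 16097 genes. The comparisons were MCF-7RR minus MCF-7, MDA-MB-231RR minus MDA-MB-231, the difference between these 2 changes (the MDA-MB-231 change minus the MCF-7 change, an interaction term) and MDA-MB-231 minus MCF-7 among parental cultures. Overlaps of called genes were tested with a one-sided Fisher's exact test in 4 combinations of directions, adjusted together.

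A set of 33 gene lists was fixed before the data were examined and tested with camera, limma's competitive test, at a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. They cover luminal and estrogen receptor, epithelial junction, mesenchymal, basal and myoepithelial genes; type I interferon response, MHC class I antigen presentation, NF-kB and inflammatory cytokines; p53 targets, apoptosis regulators, DNA damage checkpoint kinases, homologous recombination and Fanconi, non-homologous end joining, excision and mismatch repair; DNA replication and G1/S, mitosis, replication-dependent histones; NRF2 and antioxidant, drug efflux and detoxification, unfolded protein and integrated stress response, heat shock and protein folding; hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, cytosolic ribosome; TGF-beta and YAP targets, extracellular matrix and integrins, Notch, Wnt and stemness, immediate early genes, cancer-testis antigens; and markers of fibroblasts, immune cells, and adipocytes with endothelial cells, as other cell types. Each list was also tested with the correlation estimated from the arrays and on ranks. With an estimated correlation, camera also reads its statistic on the 4 residual degrees of freedom, which by itself raises p-values. A call lost with an estimated correlation is thus not by itself put down to genes that vary together, as the basal list below shows.

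The rule for named genes was fixed before the data were examined. For each radioresistance comparison it takes the 12 called genes with the largest rise and the 12 with the largest fall among those whose arrays do not overlap between the groups. It adds 6 shared genes per direction, the 6 genes most above and most below 0 in the difference between lines, up to 4 called members of each list discussed, a panel that separates the parental lines, and 14 genes of radiation and breast cancer research named whatever their result. The lists discussed are those called, and 6 chosen after their results were seen because members changed in either direction or bear on repair, drug efflux, inflammation or luminal identity.

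The functions were tested on simulated data before use, with array values drawn around each line's mean levels with the spread of limma's fitted prior, and 200 changed genes per comparison. For MCF-7RR against MCF-7, 62 of 66 genes changed by 2 on the log2 scale were called, 23 of 66 changed by 1, and 1 of 67 changed by 0.5, among 16081 genes tested, with 3 false calls. For MDA-MB-231RR against MDA-MB-231 the numbers were 63 of 65, 24 of 67 and 0 of 67 by limma with the same adjustment, with 7 false calls. A list raised by 0.4 was called in both, with 0 false list calls. The simulated genes varied independently and each with the same spread in every group. The simulation therefore does not test list calls among genes that vary together. Leaving out an array leaves a group with 1 array, which is then assumed to vary like the others. Alternatives covered quantile normalization and median centring of the arrays, no filter or a stricter one at the 50th percentile, a fit on only the 4 arrays compared, an intensity trend with and without a robust prior, the replicate number as a block, the mean of a gene's probe sets, a 2-fold size threshold, and leaving out each array in turn. RAD51 and STAT1 were not analysed here, and ABCB1 lay below the filter on low values.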

Results

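Transcript levels were measured on 8 whole-transcript arrays: 2 each of parental MCF-7, MCF-7RR, parental MDA-MB-231 and MDA-MB-231RR, where RR marks the derivatives kept through 15 fractions of 2 Gy. All levels below are deposited log2 values. Pearson's r across all probe sets between replicate arrays was 0.994 for parental MCF-7, 0.986 for MCF-7RR, 0.983 for parental MDA-MB-231 and 0.989 for MDA-MB-231RR. The spread between replicates was smallest in parental MCF-7, where 5 genes differed by more than 1 on the log2 scale, against 167 in MCF-7RR, 179 in parental MDA-MB-231 and 22 in MDA-MB-231RR. Replicate 1 of parental MDA-MB-231 correlated slightly more closely with replicates 1 and 2 of MDA-MB-231RR (r = 0.9835 and 0.9843) than with its own replicate (0.9830).

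The parental lines were compared first, as a check of the labels. MCF-7 carried higher levels of the luminal genes ESR1, the estrogen receptor (18.8-fold, and 3.92-fold with the mean of its probe sets), GATA3 (42.6-fold) and FOXA1 (5.93-fold), and of the epithelial adhesion genes CDH1, E-cadherin (54.0-fold), and EPCAM (27.8-fold). MDA-MB-231 carried more VIM, the mesenchymal intermediate filament vimentin (12.75 ± 0.06 against 6.19 ± 0.30, SD, n = 2 per group), and more of the transcription factor ZEB1 (10.1-fold), the growth factor receptor EGFR (11.4-fold) and the surface glycoprotein CD44 (2.19-fold). KRT18, a luminal keratin, was 4.18-fold higher in MCF-7. PGR, the progesterone receptor, stood at 5.08 ± 0.10 in MCF-7 and 4.44 ± 0.33 in MDA-MB-231 (SD, n = 2 each). All 11 differences passed the adjusted threshold of limma, the weakest being that of PGR (adjusted p = 0.0118, and 0.108 without MCF-7 parental replicate 1 or 0.0787 without MDA-MB-231 parental replicate 1). In total 6171 genes differed, 3251 higher in MDA-MB-231 and 2920 lower. With each array centred on its median the split was 2680 to 3759.

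In MCF-7RR, PEG10, an imprinted gene derived from a retrotransposon, fell about 53-fold, from 10.99 ± 0.07 to 5.26 ± 0.04 (SD, n = 2 per group). SGCE, its imprinted neighbour in the genome, fell 6.08-fold. CAV1, the main structural protein of caveolae, fell 17.7-fold, GTSF1, a factor of the piRNA pathway, fell 14.5-fold, and LDHB, a lactate dehydrogenase subunit, fell 12.2-fold. TM4SF1, a tetraspanin-like surface protein, rose 37.2-fold, from 5.94 ± 0.07 to 11.16 ± 0.62 (SD, n = 2 per group), which brought it to the level of parental MDA-MB-231 (11.05 ± 0.05, SD, n = 2). ARHGAP15, a Rac GTPase-activating protein, rose 15.7-fold and the transcription factor NFIA rose 14.5-fold.

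Among the other genes with the largest rises were the secreted or surface proteins CRISP3 (7.94-fold), CLEC3A (7.39-fold), CLCA2 (5.01-fold) and the endocytic receptor LRP2 (4.63-fold), the methyltransferase TMT1A (5.51-fold), the small nucleolar RNAs SNORA38B (5.13-fold) and SNORD116-15 (4.86-fold), and the interferon-induced genes IFI44 (5.78-fold) and IFI44L (4.68-fold). Among those with the largest falls were the interferon-induced IFIT2 (8.17-fold), the trafficking GTPase RAB31 (7.33-fold), the adhesion proteins CEACAM6 (7.11-fold) and CDH12 (7.06-fold), SYTL5 (6.37-fold), the actin-binding CNN3 (6.15-fold) and the guanine nucleotide exchange factor DOCK10 (6.00-fold). The adjusted p of these 24 genes ran from 9.42e-10 for PEG10 to 0.0172 for SNORA38B, whose MCF-7RR arrays lay far apart (10.77 ± 1.85, SD, n = 2). SNORA38B was no longer called without either parental MCF-7 array (adjusted p = 0.0564 and 0.0599), on only the 4 arrays compared (0.0795) or with a trend and robust prior (0.167). Its rise was 12.7-fold without MCF-7RR replicate 1 and 2.07-fold without replicate 2, which also left IFI44 at 3.13-fold. Replicates also lay apart for TMT1A in MCF-7RR (6.70 ± 0.95) and for SNORD116-15 in parental MCF-7 (4.44 ± 0.93, SD, n = 2 each).

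**Figure D1:**
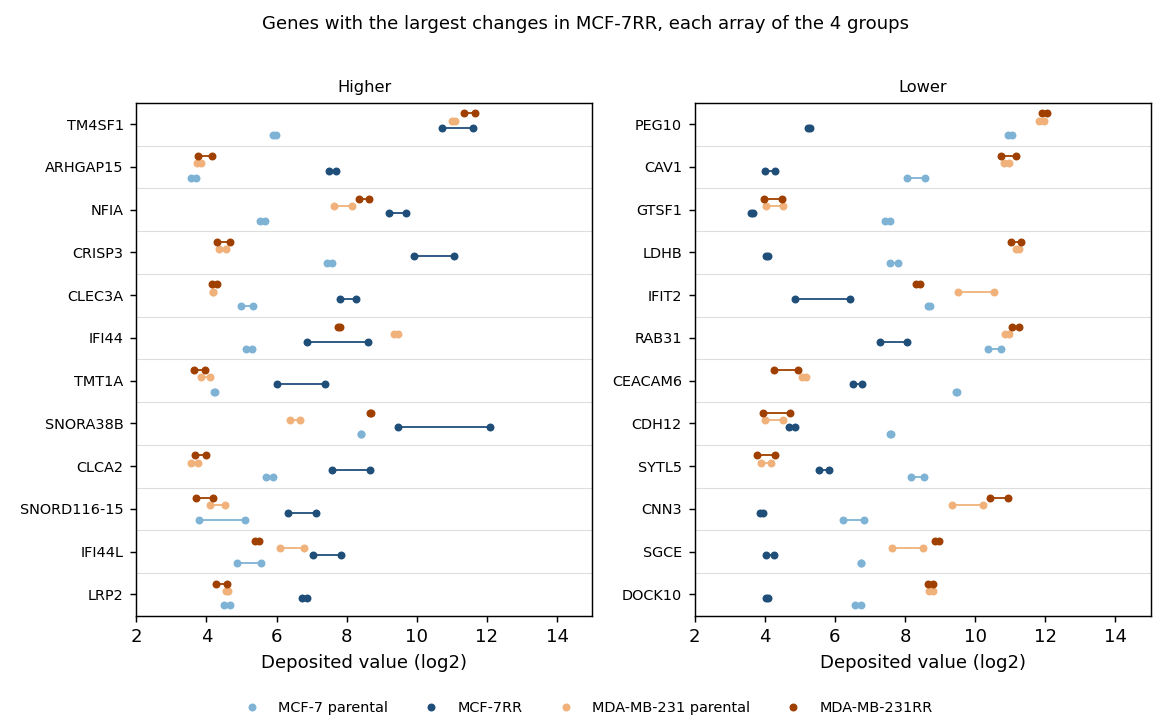
Deposited log2 values (horizontal axes) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in MCF-7RR, with 1 point per array and a line joining the 2 arrays of a group, coloured by group. PEG10 lies at 10.99 on average in MCF-7 and at 5.26 in MCF-7RR, while both MDA-MB-231 groups stay near 12; TM4SF1 moves from 5.94 to 11.16.

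In total 2154 of 16097 genes changed in MCF-7RR by limma with Benjamini-Hochberg adjustment, 765 higher and 1389 lower, and 448 of them by at least 2-fold (166 higher, 282 lower). The count was 511 without MCF-7 parental replicate 1, 481 without MCF-7 parental replicate 2 and 1109 without MCF-7RR replicate 2. Every gene called on all arrays and still tested kept its direction when any array was left out. This was largely built in. An MDA-MB-231 array left out does not alter the MCF-7RR change, and a called gene could hardly reverse without a single array of its own line.

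Of 40 DNA replication genes tested, 12 fell and 0 rose in MCF-7RR by limma (17 and 0 adjusted over the list alone; 20 passed an unadjusted p of 0.05). They included CDC6, which loads the replicative helicase (2.15-fold), the helicase component CDC45 (2.02-fold), the clamp loader subunit RFC2 (2.02-fold) and MCM10 (1.97-fold). The list's median change was -0.36 on the log2 scale (camera adjusted p = 1.43e-05, but adjusted p = 0.884 with an estimated correlation). Of 38 mitosis genes, 11 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of -0.29. The cytokinesis scaffold ANLN fell 3.25-fold, HMMR fell 1.79-fold and CKAP2L fell 1.73-fold, while the kinetochore gene CENPF rose 2.02-fold. This list's call (adjusted p = 0.0320) depended on 2 of the 4 arrays compared, with an adjusted p of 0.496 and a median of -0.13 without MCF-7RR replicate 1 and an adjusted p of 0.0710 without MCF-7 parental replicate 1. It was also lost under quantile normalization (0.127), with the stricter filter (0.0670) and by adjusted p = 0.884 with an estimated correlation. Without MCF-7 parental replicate 1 or 2, HMMR reached an adjusted p of 0.0817 and 0.0538 and CKAP2L 0.0666 and 0.109, and CKAP2L reached 0.0510 without MCF-7RR replicate 1. MKI67, the proliferation marker, fell 1.70-fold (adjusted p = 0.00803, and 0.102 or 0.0712 without the first or the second parental array).

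Of 28 hypoxia and glycolysis genes, 7 rose and 0 fell in MCF-7RR by limma (9 and 2 adjusted over the list alone; 15 passed an unadjusted p of 0.05), with a median of 0.36 (adjusted p = 0.000785, but adjusted p = 0.884 with an estimated correlation). They included the vasodilator peptide ADM (2.13-fold), the histone demethylase KDM3A (1.95-fold), the glycolytic regulator PFKFB3 (1.92-fold) and the mitophagy receptor BNIP3 (1.79-fold). The list's median was 0.09 in MCF-7RR replicate 1 and 0.68 in replicate 2, each against the parental mean. These 4 calls ended without MCF-7 parental replicate 2 (adjusted p from 0.0532 to 0.102), those of ADM, KDM3A and BNIP3 also without MCF-7RR replicate 2 (0.0584, 0.0583 and 0.0595), and those of ADM and BNIP3 without MCF-7 parental replicate 1 (0.0512 and 0.0538).

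Of 21 mesenchymal genes, 3 fell and 0 rose in MCF-7RR by limma (7 and 0 adjusted over the list alone; 10 passed an unadjusted p of 0.05). These were CAV1, the membrane-cytoskeleton linker MSN (4.15-fold) and VIM (2.17-fold), and the median was -0.27. Of 9 basal and myoepithelial genes, the integrin ITGA6 fell (2.78-fold) and 0 rose by limma (1 and 0 adjusted over the list alone; 2 passed an unadjusted p of 0.05), with a median of -0.37. Of 18 cholesterol synthesis genes, SQLE, squalene epoxidase, fell (1.77-fold) and 0 rose by limma (1 and 0 adjusted over the list alone; 8 passed an unadjusted p of 0.05), with a median of -0.33. The camera adjusted p was 0.0320 for the mesenchymal and basal lists and 0.0477 for cholesterol synthesis. Each list reached adjusted p = 0.884 with an estimated correlation. The basal list's estimated correlation was -0.011, below the preset 0.01, yet its unadjusted camera p rose from 0.00416 to 0.0408. The test with an estimated correlation reads its statistic on only the 4 residual degrees of freedom. A call lost with an estimated correlation therefore does not by itself show that genes varying together had produced it. Without MCF-7RR replicate 1 the basal median was -0.22. Without MCF-7RR replicate 2 the mesenchymal list reached 0.137 and the basal list 0.0524, without MCF-7 parental replicate 2 the basal list reached 0.0555, and the cholesterol list was lost without either parental array (0.0529 and 0.128) or without MCF-7RR replicate 1 (0.277). SQLE was not called in these same 3 cases (0.0825, 0.111 and 0.0592), nor VIM without MCF-7 parental replicate 1 (0.0530). With the stricter filter all 3 lists reached 0.0670, on ranks the mesenchymal list reached 0.0716, and the cholesterol list reached 0.0831 under quantile normalization and 0.0510 with the mean of the probe sets.

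Interferon-induced genes went both ways in MCF-7RR: 4 of 34 rose and 10 fell (5 and 11 adjusted over the list alone), and the list was not called (adjusted p = 0.304, median -0.09). IFI44 and IFI44L rose, as given above, whereas IFIT2 and the ISG15 ligase HERC5 (3.62-fold) fell. IFIT2 stood at 5.65 ± 1.12 in MCF-7RR (SD, n = 2). Drug efflux and detoxification genes also split, with 4 of 20 higher and 5 lower (6 and 8 adjusted over the list alone; adjusted p = 0.489): the glutathione transferase GSTP1 fell 3.48-fold and the transporters ABCC2 and ABCC4 fell 2.64-fold and 2.24-fold, while the glutathione transferase GSTM3 rose 2.68-fold (not called without MCF-7 parental replicate 1, 0.0604, or MCF-7RR replicate 2, 0.0832, where it was 1.89-fold). Of 22 homologous recombination and Fanconi genes, 1 rose and 4 fell (3 and 8 adjusted over the list alone; adjusted p = 0.304). RAD52 rose 1.57-fold, and FANCL, BRCA1 and XRCC3 fell 1.57-fold, 1.53-fold and 1.48-fold. Each of these 4 calls ended when any MCF-7 or MCF-7RR array was left out (adjusted p from 0.0606 to 0.245).

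In MDA-MB-231RR, SCD, the stearoyl-CoA desaturase of fatty acid synthesis, rose 10.5-fold, from 6.57 ± 0.14 to 9.97 ± 0.00 (SD, n = 2 per group). Immediate early transcription factors rose with it: FOS 8.52-fold, EGR1 7.04-fold, NR4A2 5.81-fold and FOSB 5.04-fold, along with the phosphatase DUSP1 (4.38-fold). The kinase WEE1, which restrains entry into mitosis, rose 4.30-fold. H2BC14, a replication-dependent histone gene, fell 17.9-fold, from 10.01 ± 0.69 to 5.85 ± 0.19 (SD, n = 2 per group). The chemokines CXCL10, CXCL11 and CCL5 fell 7.69-fold, 4.92-fold and 4.81-fold, and the interferon-induced genes OASL, IFIT1 and RSAD2 fell 6.57-fold, 5.10-fold and 4.67-fold.

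The other genes with the largest rises were the synaptic adhesion gene SLITRK6 (8.04-fold), the small nucleolar and Cajal body RNAs SCARNA4 (8.01-fold), SNORA62 (5.57-fold) and SNORD20 (5.11-fold), and the readthrough gene KLRC4-KLRK1 (4.16-fold). The other largest falls were of the histone genes H2AC13 (6.31-fold) and H3C12 (4.13-fold), CDA, cytidine deaminase (5.68-fold), KIAA0040 (4.06-fold) and the adhesion receptor ADGRF1 (3.93-fold). The adjusted p of the 24 genes ran from 5.20e-07 for SCD to 0.0230 for IFIT1. A further WEE1 probe set rose with the one used (2.36 on the log2 scale), and another changed less (0.41). Calls of IFIT1, SLITRK6 and KLRC4-KLRK1 ended without MDA-MB-231 parental replicate 2 (adjusted p = 0.0895, 0.0593 and 0.122) and without either MDA-MB-231RR array (from 0.0653 to 0.213), and that of IFIT1 also without MDA-MB-231 parental replicate 1 (0.0698) and with median centring (0.0632). With a trend and robust prior the 3 genes reached 0.160, 0.0764 and 0.0835. The rise of KLRC4-KLRK1 was 2.59-fold without MDA-MB-231 parental replicate 2.

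**Figure D2:**
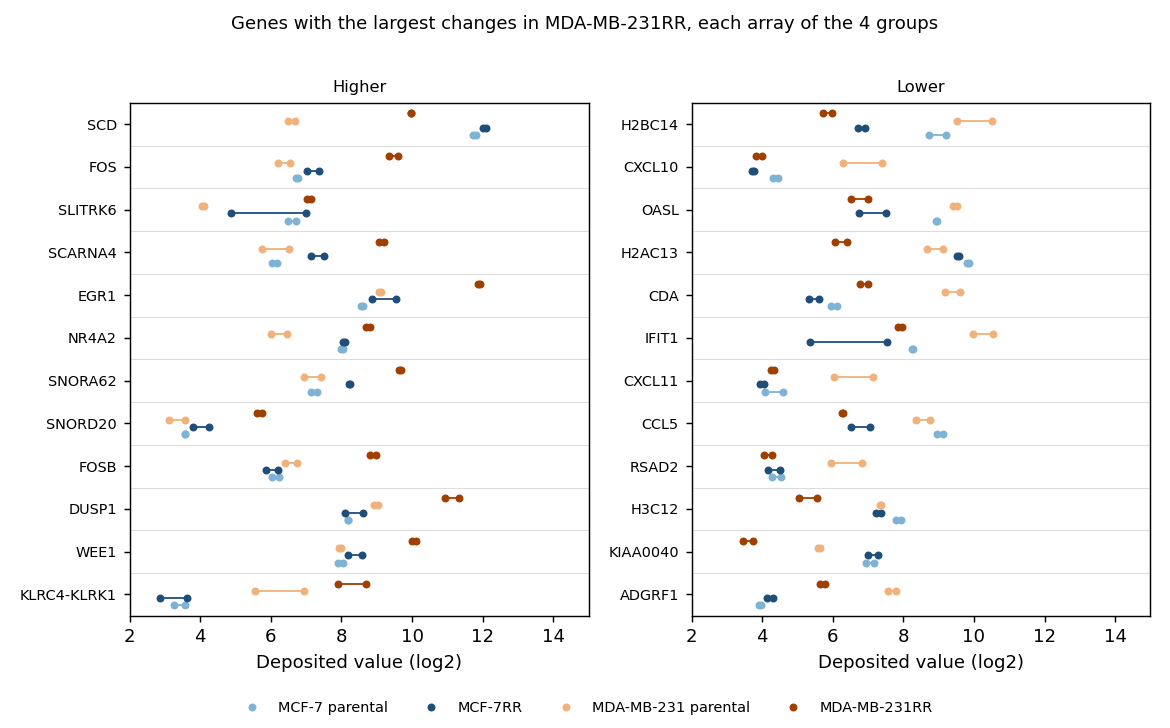
Deposited log2 values (horizontal axes) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in MDA-MB-231RR, with 1 point per array and a line joining the 2 arrays of a group, coloured by group. SCD moves from 6.57 to 9.97 in MDA-MB-231 and lies near 12 in both MCF-7 groups; H2BC14 falls from 10.01 to 5.85.

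In total 548 of 16097 genes changed in MDA-MB-231RR by limma with Benjamini-Hochberg adjustment, 349 higher and 199 lower, and 191 of them by at least 2-fold (120 higher, 71 lower). With each array centred on its median the split was 448 to 143. The count was 96 and 117 without MDA-MB-231RR replicate 1 and 2, 170 without MDA-MB-231 parental replicate 2, 1486 without MDA-MB-231 parental replicate 1, and 340 and 339 without MCF-7 parental replicate 1 and 2. Among genes with a mean above 8, 97 were over 2-fold lower in parental replicate 2 than in parental replicate 1 and 1 was higher, and across genes at that level the MDA-MB-231RR change correlated with gene length (Spearman's rho = 0.261; genes are not independent replicates).

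Of 34 interferon response genes, 15 fell and 0 rose in MDA-MB-231RR by limma (27 and 0 adjusted over the list alone; 27 passed an unadjusted p of 0.05). OASL, IFIT1 and RSAD2 were among them, as was the RNA sensor IFIH1 (3.80-fold). The list's median change was -0.89 (adjusted p = 8.76e-17, but adjusted p = 0.272 with an estimated correlation). Against parental replicate 1 alone the median was -1.14, and against parental replicate 2 alone -0.91. Of 15 immediate early genes, 5 rose and 0 fell by limma (7 and 0 adjusted over the list alone; 7 passed an unadjusted p of 0.05), with a median of 0.37 (adjusted p = 2.42e-08, but adjusted p = 0.272 with an estimated correlation). Of 25 NF-kB and inflammatory cytokine genes, 5 rose and 5 fell (6 and 6 adjusted over the list alone; adjusted p = 0.536). The cytokine IL1B and the chemokine CXCL8 rose 3.45-fold and 2.95-fold, and the chemokines CXCL10 and CCL5 fell.

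Of 18 fatty acid synthesis genes, 3 rose and 0 fell in MDA-MB-231RR by limma (7 and 0 adjusted over the list alone; 8 passed an unadjusted p of 0.05): SCD, the desaturase FADS2 (2.32-fold) and the regulator SREBF1 (1.83-fold). Of 18 cholesterol synthesis genes, 3 rose and 0 fell by limma (7 and 0 adjusted over the list alone; 7 passed an unadjusted p of 0.05): the regulator SREBF2 (1.99-fold), INSIG1 (1.77-fold) and the synthase HMGCS1 (1.72-fold). The medians were 0.25 and 0.25, with camera adjusted p of 0.000115 and 0.00146. These became adjusted p = 0.437 and adjusted p = 0.602 with an estimated correlation. The cholesterol median was 0.16 without MDA-MB-231 parental replicate 1 and 0.38 without parental replicate 2. The calls of SREBF1, SREBF2, INSIG1 and HMGCS1 ended without either MDA-MB-231RR array (adjusted p from 0.101 to 0.209), the first 3 also without MDA-MB-231 parental replicate 2 (0.0645, 0.0696 and 0.105), and HMGCS1 without parental replicate 1 of either line or MCF-7 parental replicate 2 (0.0926, 0.0610 and 0.0610).

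Of 38 mitosis genes, 2 rose and 0 fell in MDA-MB-231RR by limma (9 and 0 adjusted over the list alone; 18 passed an unadjusted p of 0.05). These were ASPM (1.93-fold) and CENPF (1.72-fold), and the list's median was 0.38 (adjusted p = 2.15e-08, but adjusted p = 0.437 with an estimated correlation). The median was 0.31 against parental replicate 1 alone, and 0.25 after a trend with gene length and level was removed. Both single calls ended without MDA-MB-231 parental replicate 2 (adjusted p = 0.222 and 0.154) or either MDA-MB-231RR array (0.146 to 0.238), ASPM's with median centring (0.0518), and CENPF's without either MCF-7 parental array (0.0605 each). Of 28 hypoxia and glycolysis genes, KDM3A rose (1.75-fold) and the vascular growth factor VEGFA, which had risen 1.67-fold in MCF-7RR, fell (1.54-fold), with 7 and 1 adjusted over the list alone and a median of 0.24 (adjusted p = 0.000372, but adjusted p = 0.602 with an estimated correlation). Both calls ended without MDA-MB-231 parental replicate 2 (adjusted p = 0.140 and 0.0994), without either MCF-7 parental array (0.0622 to 0.0947) or without either MDA-MB-231RR array (from 0.134 to 0.247), KDM3A's also without MDA-MB-231 parental replicate 1 (0.0752), and VEGFA's with median centring (0.0601) and on only the 4 arrays compared (0.0961).

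Of 22 TGF-beta and YAP targets, 3 rose and 1 fell in MDA-MB-231RR (6 and 1 adjusted over the list alone): the growth factor TGFB2 (1.98-fold), ID3 (1.88-fold) and the matricellular CCN1 (1.72-fold) rose, and the transglutaminase TGM2 fell (1.77-fold). The median was 0.34 (adjusted p = 0.0106, but adjusted p = 0.437 with an estimated correlation). The list was lost without MDA-MB-231 parental replicate 2 (median 0.15, 0.241) or MDA-MB-231RR replicate 1 (median 0.21, 0.282), and TGFB2 and ID3 were not called under quantile normalization (0.0539 and 0.0704). The calls of all 4 genes ended without MDA-MB-231 parental replicate 2 (0.0529 to 0.253) or MDA-MB-231RR replicate 1 (0.0728 to 0.327). Calls ended for TGFB2, TGM2 and CCN1 without MDA-MB-231RR replicate 2 (0.161, 0.0942 and 0.0898), TGFB2's without MDA-MB-231 parental replicate 1 (0.0599). ID3's ended with median centring (0.0778) or when any MCF-7 or MCF-7RR array was left out (0.0518 to 0.0595). Of 17 replication-dependent histone genes tested, 4 fell and 0 rose by limma (5 and 0 adjusted over the list alone; 5 passed an unadjusted p of 0.05): H2BC14, H4C3 (2.09-fold), H2AC17 (1.86-fold) and H3C2 (1.76-fold). Their median was -0.15 (adjusted p = 0.0269, but adjusted p = 0.437 with an estimated correlation), and the call was lost on ranks (0.154), without MDA-MB-231 parental replicate 1 (0.338) and without MDA-MB-231RR replicate 2 (0.123, median -0.09). With median centring the median was -0.06. The calls of H4C3, H2AC17 and H3C2 ended without MDA-MB-231 parental replicate 2 (0.0632, 0.179 and 0.140) or MDA-MB-231RR replicate 2 (0.138, 0.144 and 0.159), those of H4C3 and H2AC17 without MDA-MB-231RR replicate 1 (0.107 and 0.188). H3C2's ended without either MCF-7 parental array (0.0529 and 0.0530) or with median centring (0.0746).

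Of 16 epithelial junction genes, the claudin CLDN7 (2.02-fold) and CDH1 (1.93-fold) fell in MDA-MB-231RR and the epithelial transcription factor ELF3 rose (1.68-fold), with 4 lower and 1 higher adjusted over the list alone. The median was -0.32 (adjusted p = 0.0240, but adjusted p = 0.602 with an estimated correlation), and the list was not called under quantile normalization (0.0793) or without MDA-MB-231 parental replicate 1 (0.148). Markers of fibroblasts, immune cells, and adipocytes with endothelial cells, not called as lists, had medians of -0.25, -0.21 and -0.19 there, and long non-coding RNAs -0.21. A median below 0 was thus not particular to the epithelial list. The 25th percentile of all values was 4.66 and 4.86 in parental replicates 1 and 2, and 4.60 and 4.74 in MDA-MB-231RR. Without MDA-MB-231RR replicate 1 the epithelial median was -0.19. Without that array, CLDN7, CDH1 and ELF3 reached 0.0830, 0.108 and 0.112. ELF3 was not called without MDA-MB-231 parental replicate 2 (0.125), MDA-MB-231RR replicate 2 (0.150) or either MCF-7 parental array (0.0561 each). Drug efflux and detoxification genes were not called as a list (adjusted p = 0.888): the cytochromes CYP1B1 and CYP1A1 fell 3.39-fold and 2.26-fold and the lipid transporter ABCA1 rose 2.47-fold, with 1 higher and 2 lower of 20 (the same counts adjusted over the list alone). Their calls ended without MDA-MB-231RR replicate 1 (0.0728, 0.231 and 0.0538), CYP1B1's without MDA-MB-231RR replicate 2 (0.0636) and CYP1A1's without MDA-MB-231 parental replicate 2 (0.177).

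**Figure D3:**
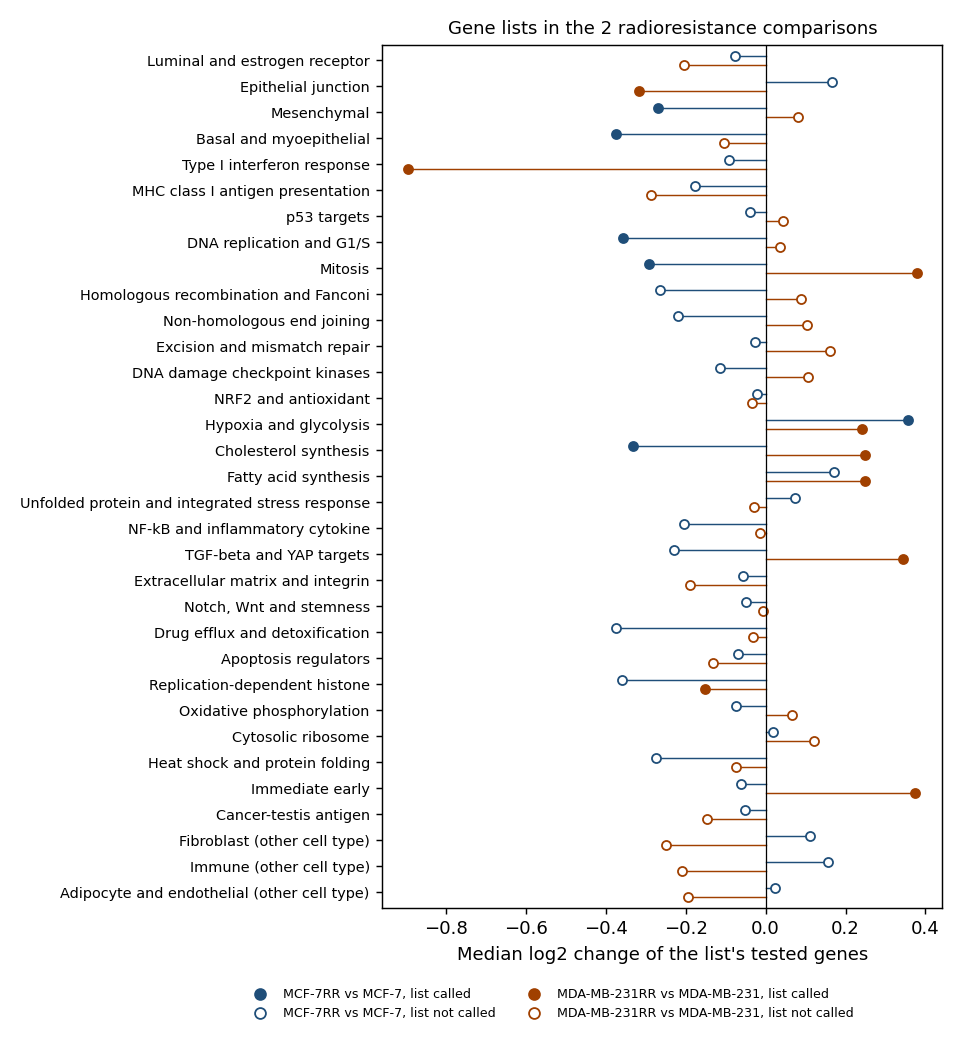
Median log2 change of the tested genes of each of the 33 lists (horizontal axis), radioresistant minus parental, for MCF-7 (blue) and MDA-MB-231 (brown), with filled points where camera called the list at the preset correlation of 0.01. The interferon list lies at -0.89 in MDA-MB-231RR and at -0.09 in MCF-7RR; with an estimated correlation 0 lists were called in either line, and 1 and 2 lists passed an unadjusted p of 0.05.

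The remaining lists were not called, and the counts that follow are members higher and lower, with those adjusted over the list alone in parentheses. In MCF-7RR these were 1 and 2 of 20 luminal and estrogen receptor genes (3 and 3), 2 and 3 of 26 p53 targets (3 and 3), 4 and 2 of 26 NRF2 and antioxidant genes (4 and 3), 5 and 3 of 26 unfolded protein and integrated stress response genes (5 and 4), 4 and 6 of 33 extracellular matrix and integrin genes (4 and 7), 1 and 5 of 26 Notch, Wnt and stemness genes (1 and 5), 1 and 2 of 25 apoptosis regulators (1 and 3), 1 and 4 of 17 replication-dependent histones (1 and 5), 4 and 3 of 31 cytosolic ribosome genes (4 and 3), 1 and 3 of 16 heat shock and protein folding genes (1 and 4), 1 and 1 of 18 fatty acid synthesis genes (1 and 1) and 2 and 2 of 9 cancer-testis antigens (2 and 2). Falls alone were called for 2 of 13 non-homologous end joining genes (2), 1 of 27 excision and mismatch repair genes (0), 3 of 19 checkpoint kinases (3), 2 of 22 TGF-beta and YAP targets (5, with 1 higher), 1 of 28 oxidative phosphorylation genes (1), 1 of 15 immediate early genes (1) and 1 of 25 NF-kB and inflammatory cytokine genes (1), which was CCL5. Of 11 MHC class I antigen presentation genes 1 rose (0 adjusted over the list alone). By limma 0 genes were called among 16 epithelial junction genes and the 7, 11 and 12 markers of fibroblasts, immune cells and adipocytes with endothelial cells, where 5, 1, 0 and 4 passed an unadjusted p of 0.05. The adjusted p of the 27 uncalled lists ran from 0.144 to 0.931.

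In MDA-MB-231RR, the same counts were 1 and 2 of 20 luminal and estrogen receptor genes (1 and 2), 1 and 1 of 19 checkpoint kinases (2 and 1), 2 and 2 of 33 extracellular matrix and integrin genes (3 and 3) and 3 and 1 of 26 Notch, Wnt and stemness genes (3 and 1). Rises alone were called for 3 of 26 p53 targets (5, with 1 lower), 3 of 26 unfolded protein and integrated stress response genes (4), 1 of 21 mesenchymal genes (3, with 1 lower) and 1 of 13 non-homologous end joining genes (1). Falls alone were called for 1 of 40 DNA replication genes (1), 1 of 26 NRF2 and antioxidant genes (1), 1 of 11 MHC class I antigen presentation genes (5, with 2 higher), 1 of 25 apoptosis regulators (2, with 2 higher) and 1 of 16 heat shock and protein folding genes (2). By limma 0 genes were called among 9 basal, 22 homologous recombination, 27 excision and mismatch repair, 28 oxidative phosphorylation and 31 cytosolic ribosome genes, where 1, 4, 8, 9 and 6 passed an unadjusted p of 0.05, and among 9 cancer-testis antigens and the 7, 11 and 12 markers of fibroblasts, immune cells and adipocytes with endothelial cells, where 2, 1, 1 and 2 did (1 immune marker was lower when adjusted over the list alone). The adjusted p of the 24 uncalled lists ran from 0.0765 to 0.888. Median and test differed in sign for p53 targets, excision repair, NRF2, cancer-testis and adipocyte lists in MCF-7RR, for the unfolded protein, NF-kB, Notch and drug efflux lists in MDA-MB-231RR, and mean and test for fibroblast markers in MCF-7RR.

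Luminal genes that were called included CA12, carbonic anhydrase 12, which rose 2.01-fold in MCF-7RR and 2.76-fold in MDA-MB-231RR, and the transcription factor MYB, which fell 1.79-fold and 1.64-fold. PGR fell 2.24-fold in MCF-7RR and SPDEF fell 2.01-fold in MDA-MB-231RR. Among histones, H2BC12 fell 2.69-fold and H4C8 rose 1.58-fold in MCF-7RR, where H3C2 fell 1.58-fold. Calls of MYB, H3C2 and H4C8 in MCF-7RR and of MYB in MDA-MB-231RR ended without either MCF-7 parental array (adjusted p from 0.0597 to 0.257). H3C2 also ended without either MCF-7RR array (0.0755 and 0.113). H4C8 ended without MCF-7RR replicate 1 (0.221), without either MDA-MB-231RR array (0.0544 and 0.0546), with median centring (0.0542) and on only the 4 arrays compared (0.0644). MYB in MDA-MB-231RR ended when any of the 8 arrays was left out (0.0512 to 0.313), with quantile normalization (0.0502), median centring (0.0572) and the 4 arrays compared (0.0722). SPDEF ended without MDA-MB-231 parental replicate 2 (0.0645) or MDA-MB-231RR replicate 2 (0.0942).

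ESR1 stood at 9.45 ± 0.12 in MCF-7 and 8.79 ± 0.01 in MCF-7RR (SD, n = 2 each; adjusted p = 0.0583). It was called lower in MCF-7RR under quantile normalization (0.0453), median centring (0.0283), a fit on only the 4 arrays compared (0.0215), a trend and robust prior (0.0476) and without either parental MDA-MB-231 array (0.0156 and 0.0155), while a second ESR1 probe set gave a change of 0.21 on the log2 scale. In MDA-MB-231RR, ESR1 changed by -0.41 (adjusted p = 0.278), and by -0.77 without MDA-MB-231 parental replicate 1 (0.0314). BCL2, an inhibitor of apoptosis, rose 2.91-fold in MCF-7RR (adjusted p = 0.000150), and was not called in MDA-MB-231RR (adjusted p = 0.992). CDH1 changed by 0.43 in MCF-7RR (adjusted p = 0.0925, and 0.0495 on only the 4 arrays compared), VIM by 0.30 and MKI67 by 0.24 in MDA-MB-231RR (0.370 and 0.369). For ERBB2, EGFR, CDKN1A, CHEK1 and ABCG2 no change was called in either line, with log2 changes of 0.37, -0.39, -0.31, -0.11 and -0.65 in MCF-7RR and -0.03, -0.31, -0.16, -0.04 and -0.01 in MDA-MB-231RR. ABCG2 in MCF-7RR lay at the threshold (adjusted p = 0.0515, 0.0246 without MCF-7RR replicate 2, 0.0367 and 0.0365 without the parental MDA-MB-231 arrays, 0.0444 with an intensity trend and 0.0366 with a robust prior added). ATM changed by 0.15 in MCF-7RR and 0.70 in MDA-MB-231RR (adjusted p = 0.0593, 0.0203 without MDA-MB-231 parental replicate 1, and 0.0473 and 0.0389 with an intensity trend and with a robust prior added).

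Of the genes that fell in both lines, the chemokine CCL5 fell 4.77-fold in MCF-7RR and 4.81-fold in MDA-MB-231RR, HERC5 fell 3.62-fold and 3.73-fold, IFIT3 fell 3.59-fold and 3.53-fold, OASL fell 3.53-fold and 6.57-fold, and IFIT1 fell 3.51-fold and 5.10-fold. H2BC14 fell 4.48-fold and 17.9-fold. In MCF-7RR the call of IFIT1 ended with median centring (adjusted p = 0.0528), on only the 4 arrays compared (0.0971), with a trend and robust prior (0.176) and without either MCF-7 parental array (0.0964 and 0.0928), MCF-7RR replicate 2 (0.0926) or either MDA-MB-231RR array (0.0586 and 0.0591). The fall of IFIT1 there was 1.65-fold without MCF-7RR replicate 2 and 7.47-fold without replicate 1, and that of IFIT3 was 2.26-fold without replicate 2. IFIT3 in MDA-MB-231RR was lost without MDA-MB-231 parental replicate 2 (0.0527) or either MDA-MB-231RR array (0.160 and 0.0955). Of genes that rose in each, SESN3, a stress-induced sestrin, rose 4.09-fold and 3.36-fold, LIMCH1 rose 1.99-fold and 3.19-fold, the lipoprotein receptor VLDLR rose 1.98-fold and 2.12-fold, SCARNA4 rose 2.32-fold and 8.01-fold, and SNORA62 rose 1.99-fold and 5.57-fold. In MCF-7RR, CA12 was not called without MCF-7 parental replicate 2 or MCF-7RR replicate 2 (0.0635 and 0.0585), SCARNA4 without MCF-7RR replicate 2 (0.0521), SNORA62 without MCF-7 parental replicate 1 (0.0569). LIMCH1 was not called when any array of the line was left out (0.0860 to 0.133) or with median centring (0.0677). In MDA-MB-231RR, LIMCH1 was lost without replicate 1 (0.0951) and VLDLR without replicate 1 or 2 (0.0548 and 0.0575).

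Altogether 44 genes fell in both lines, against 17.2 expected for independent lists (one-sided Fisher's exact test, adjusted p = 1.76e-08), and 25 rose in both, against 16.6 expected (adjusted p = 0.0546). By the same test, opposite changes were found for 39 genes lower in MCF-7RR and higher in MDA-MB-231RR (30.1 expected, adjusted p = 0.0760). The reverse order was found for 12 genes (9.46 expected, adjusted p = 0.238). Counts thus lay above expectation in every combination of directions. Both comparisons took a gene's spread from the same shared estimate, so their calls are not independent. The test also treats genes that change together, such as interferon genes, as separate draws. These p-values may therefore be too small. Across all 16097 genes the changes of the 2 lines were close to unrelated (Pearson's r = -0.045, Spearman's rho = -0.087; genes are not independent replicates). The count of 69 same-direction genes was 26, 22, 41, 116, 39, 21 and 23 without MCF-7 parental replicate 1, MCF-7 parental replicate 2, MCF-7RR replicate 2, MDA-MB-231 parental replicate 1, MDA-MB-231 parental replicate 2, MDA-MB-231RR replicate 1 and MDA-MB-231RR replicate 2.

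The change itself differed between the lines for 1589 genes, 1007 with a higher and 582 with a lower change in MDA-MB-231. PEG10, CAV1, GTSF1, LDHB and CNN3 fell in MCF-7RR, with log2 changes of 0.08, 0.07, -0.05, -0.05 and 0.91 in MDA-MB-231RR that were not called. GTSF1 lay at 4.28 and 4.23 in the MDA-MB-231 groups, below the filter value of 4.67, and at 3.64 in MCF-7RR. A fall as large as that in MCF-7RR could thus not show in MDA-MB-231RR. SLITRK6 rose in MDA-MB-231RR, with -0.66 in MCF-7RR that was not called. Their differences ran from 3.53 to 5.81 (adjusted p from 4.93e-08 to 0.00590), and that of SLITRK6 was lost with a trend and robust prior (0.0669). TM4SF1, ARHGAP15, NFIA, IFI44L and CRISP3 rose in MCF-7RR and were not called in MDA-MB-231RR (adjusted p = 0.298, 0.564, 0.129, 0.0863 and 0.959). IFI44 rose in MCF-7RR and fell 3.09-fold in MDA-MB-231RR. Differences of these 6 ran from -4.77 to -2.96. TM4SF1 already stood at 11.05 in parental MDA-MB-231, where a rise as large as that in MCF-7RR would pass the largest deposited value. Such a rise could thus not show in MDA-MB-231RR. With each array centred on its median the split was 1681 to 534 and the median over all genes was 0.12, against -0.01 as deposited. The count was 527 and 549 without MCF-7 parental replicate 1 and 2, 586 and 961 without MDA-MB-231RR replicate 1 and 2, and 2577 without MDA-MB-231 parental replicate 1.

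Of the 33 lists, 10 differed between the lines. Changes were higher in MDA-MB-231 for mitosis (median difference 0.63, adjusted p = 5.49e-07), DNA replication (0.42, 1.06e-05), immediate early genes (0.74, 1.40e-05), cholesterol synthesis (0.75, 0.000348), mesenchymal genes (0.34, 0.00748), TGF-beta and YAP targets (0.52, 0.0264) and checkpoint kinases (0.28, 0.0427). These became adjusted p = 0.573 with an estimated correlation for cholesterol synthesis and adjusted p = 0.505 with an estimated correlation for each of the other 6. Changes were lower for the interferon response (-0.63, 7.43e-06), epithelial junctions (-0.37, 0.0227) and immune cell markers (-0.39, 0.0427). These became adjusted p = 0.505, adjusted p = 0.573 and adjusted p = 0.812 with an estimated correlation, so 0 of the 33 lists were called, and 1 passed an unadjusted p of 0.05. Markers of fibroblasts and of adipocytes with endothelial cells, not called, had median differences of -0.21 and -0.13. Without MCF-7RR replicate 1 the interferon, mesenchymal and TGF-beta medians were -0.33, 0.59 and 0.29, and with the stricter filter the mesenchymal median was 0.52. The epithelial median was -0.24 with median centring and -0.23 without MDA-MB-231RR replicate 1, and the immune median -0.25 with median centring and -0.22 without MDA-MB-231 parental replicate 2. The calls for TGF-beta and YAP targets, checkpoint kinases and immune markers ended under quantile normalization (0.0663, 0.184 and 0.0938), and that for TGF-beta and YAP targets with median centring (0.0886), with the stricter filter (0.0903) and on ranks (0.0564). Without MDA-MB-231RR replicate 1, 6 lists were called, and mesenchymal genes, checkpoint kinases, TGF-beta and YAP targets and immune markers were lost (0.0812, 0.0812, 0.179 and 0.158). Without MDA-MB-231 parental replicate 2 the last 3 were lost (0.0765, 0.213 and 0.113), and without parental replicate 1 the epithelial list (0.0868) and checkpoint kinases (0.0526). Checkpoint kinases also ended with the stricter filter (0.119) and without MCF-7 parental replicate 1 (0.0816) or MCF-7RR replicate 1 (0.0951). Immune markers ended without the filter (0.0529), MCF-7 parental replicate 2 (0.0704) or either MCF-7RR array (0.0531 and 0.0741).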

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

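Except for the differences between the lines, which were planned, the tests in this part were chosen after the results were seen. The changes differed between the lines at 1589 genes by the interaction term. Among lists, the median difference (MDA-MB-231 change minus MCF-7 change, log2) was 0.75 for cholesterol synthesis, 0.74 for immediate early genes, 0.63 for mitosis, 0.52 for TGF-beta and YAP targets, 0.42 for DNA replication, 0.34 for mesenchymal genes, 0.28 for checkpoint kinases, -0.37 for epithelial junctions, -0.39 for immune markers and -0.63 for the interferon response. With an estimated correlation 0 of all 33 lists were called by camera and 1 passed an unadjusted p of 0.05 (lowest adjusted p = 0.505 with an estimated correlation), and the calls for TGF-beta and YAP targets, checkpoint kinases and immune markers also ended under quantile normalization and without single arrays.

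Of 121 named genes tested, 75 differed between the lines, 49 with the change higher in MDA-MB-231 and 26 with it lower. Many of these genes were named for a large change in 1 line or for this difference itself, so a high share was built in. Over all genes tested, 1589 of 16097 differed (9.87%). The highest differences (log2) were PEG10 5.81, CAV1 4.21, GTSF1 3.81, SLITRK6 3.66, LDHB 3.56, CNN3 3.53, SGCE 3.44, RAB31 3.11, SCD 3.10, CDH12 2.90, SYTL5 2.66, FOS 2.64 and DOCK10 2.57. Next came NR4A2 2.49, FOSB 2.44, CEACAM6 2.33, KLRC4-KLRK1 2.22, EGR1 2.19, ANLN 2.15, CXCL8 1.98, DUSP1 1.96, IL1B 1.95, SNORD20 1.91, SCARNA4 1.79, ABCA1 1.71, WEE1 1.69, MSN 1.68 and GSTP1 1.66. The remaining ones above 0 were ID3 1.58, ITGA6 1.49, SNORA62 1.48, FADS2 1.44, VIM 1.42, CKAP2L 1.38, SREBF2 1.36, H2BC12 1.33, ABCC4 1.23, MCM10 1.16, HMGCS1 1.12, ABCC2 1.12, SQLE 1.06, MKI67 1.00, PGR 0.99, CDC6 0.98, CDC45 0.98, RFC2 0.98, FANCL 0.91, HMMR 0.90 and CCN1 0.78. Below 0 were TM4SF1 -4.77, IFI44 -4.16, ARHGAP15 -3.80, NFIA -3.25, IFI44L -3.22, CRISP3 -2.96, CLEC3A -2.83, SNORD116-15 -2.65, TMT1A -2.64, H2AC13 -2.38, LRP2 -2.38, CXCL10 -2.30 and ADGRF1 -2.26. The others below 0 were RSAD2 -2.15, CLCA2 -2.14, KIAA0040 -2.09, H2BC14 -2.00, CXCL11 -1.97, CDA -1.93, BCL2 -1.54, H3C12 -1.48, CDH1 -1.38, VEGFA -1.36, IFIH1 -1.20, RAD52 -0.98 and H2AC17 -0.98. GTSF1, CDH12, SYTL5 and PGR fell in MCF-7RR but lay below the filter value of 4.67 in both MDA-MB-231 groups, and CXCL10, CXCL11, RSAD2 and ADGRF1 fell in MDA-MB-231RR but lay below it in both MCF-7 groups. Lower readings do occur below that value, as CXCL10 read 4.38 in MCF-7 and 3.73 in MCF-7RR, but a large fall could not show there. These 8 differences thus do not tell a different response, as for 12 and 13 of the 1589 genes. The top of the range sets a like limit for TM4SF1, at 11.05 in parental MDA-MB-231, and for SCD, at 11.76 in parental MCF-7. A rise as large as that in the other line would pass the largest deposited value. The differences of TM4SF1 and SCD thus do not tell a different response either. This upper limit was not counted over all genes.

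Among the 9521 probe sets that carry no single gene symbol and passed the filter, 451 changed in MCF-7RR (271 higher, 180 lower) and 141 in MDA-MB-231RR (82 higher, 59 lower).

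In MCF-7RR, 49 genes changed at least 4-fold, 24 higher and 25 lower, and TM4SF1 reached the MDA-MB-231 level. MDA-MB-231 cells or RNA in these arrays would bring all abundant MDA-MB-231 transcripts, but the 97 other genes highest in MDA-MB-231 over MCF-7 had a median change of -0.25 (bootstrap 95% interval -0.42 to -0.15), which argues against it. Of the pattern's genes, 8 of the 24 that rose and 10 of the 25 that fell are at least 2-fold higher in MDA-MB-231 than in MCF-7. Another breast cancer line in place of MCF-7RR was not excluded: its arrays correlated at r = 0.977 with MCF-7 and 0.920 with MDA-MB-231, against 0.939 between the parental lines, and no other luminal line was measured for scale. Selection by irradiation and drift in culture between separately kept cultures stay open as well, since the design does not separate them.

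In MDA-MB-231RR, 15 of 34 interferon genes were called lower and 5 of 15 immediate early genes higher, and both list calls were lost with an estimated correlation (adjusted p = 0.272 with an estimated correlation for each). Parental replicate 2 alone was argued against for the interferon list, because against parental replicate 1 only its median was -1.14 (interval -1.54 to -0.46). The intervals here resample genes, which change together, and do not measure the spread between cultures. Over all 15 immediate early genes the median against replicate 1 was 0.40, and 0.37 against both parental arrays. The 5 called ones had a median of 2.51 (lowest 0.93). Being called with both arrays made a rise over replicate 1 likely beforehand, so these 5 do not decide the question. A trend with gene length and level was argued against as the whole cause for the interferon list. After its removal the interferon median was -0.91 (interval -1.54 to -0.52). That of the 5 called immediate early genes was 2.40 (lowest 1.07). These 5 do not decide this question either, as they were picked for a large rise. Over all 15 of the list the median was 0.47, against 0.37 with the trend left in. Culture or harvest conditions that differed between dishes remain open for both sets of genes, and were not tested for the interferon genes. Immediate early genes respond to serum and handling within minutes to hours. The same 5 of them had a median of 0.17 in MCF-7RR, against -0.06 over the list. A lasting change of the radioresistant cells cannot be told apart from such a difference for either set, as it was carried by every array of the group.

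Parental replicate 2 of MDA-MB-231 stood apart from replicate 1. Among genes with a mean above 8, its difference from replicate 1 correlated with gene length (Spearman's rho = -0.16, against -0.07, 0.08 and -0.00 in the other groups), so lower RNA quality with longer genes read lower may account for part of it. MCF-7 RNA was argued against by a median of -0.043 (interval -0.13 to 0.02) for MCF-7-high genes, where a 5% share would give 0.69. Array scaling was argued against because 104 genes were still over 2-fold lower after quantile normalization, against 97 before. No biological explanation was tested for a difference between replicates.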

How the results depend on the processing

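Except for the check of replicate numbers, the settings here were planned. The 2-fold size threshold gave 448 genes in MCF-7RR, 191 in MDA-MB-231RR, 992 for the difference between lines, 2616 between parental lines and 17 shared. With the low filter at the 50th percentile 2 lists were called in MCF-7RR, and with the estimated inter-gene correlation 0, 0 and 0 lists in MCF-7RR, MDA-MB-231RR and the difference (camera; 1, 2 and 1 at an unadjusted p of 0.05). Leaving out 1 array at a time gave 481 to 2775 genes in MCF-7RR, 96 to 1486 in MDA-MB-231RR, 527 to 2577 for the difference, 21 to 116 shared genes and 6 to 11 lists for the difference. Part of this comes from the shared estimate of the spread. An array of 1 line left out does not alter the changes of the other line, yet the count there moved too. Between replicates the SD of the differences was 0.167 in parental MCF-7, 0.313 in MCF-7RR, 0.332 in parental MDA-MB-231 and 0.257 in MDA-MB-231RR. Other causes were not tested, and the number of arrays limits the precision. A group left with 1 array was assumed to vary like the others. With the replicate number as a replicate block the counts were 2513, 645, 2026 and 6531 genes, 84 shared, and 6, 9 and 10 lists, 0 of 147 named calls were lost, and ESR1 was newly called in MCF-7RR (adjusted p = 0.0487). Deviations of same-numbered arrays correlated at -0.01 in MCF-7 and 0.22 in MDA-MB-231, and the labels do not say whether a number marks a shared day, so the numbers were not taken as pairs. Of the 147 named gene calls, 91 were kept under every setting, 94 whichever array was left out and 133 under all other settings except the size threshold, and 0 changed direction. Across settings, the named gene results were unchanged in 2716 cases, newly called in 17 and no longer called in 222, and the called lists were unchanged in 394 and no longer called in 70. The difference between lines was not run on only the 4 arrays of a comparison, as it needs all 8. That 0 named calls changed direction was largely built in, because several settings leave the log2 change itself unaltered.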

Other observations

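All tests in this part were chosen after the results were seen. Of 133 small nucleolar RNAs tested, 28 rose in MDA-MB-231RR and 0 fell by limma, with a median change of 0.36 (21.1% higher, against 2.05% of protein-coding genes), and 17 rose and 4 fell in MCF-7RR (12.8% against 4.55%), with a median of 0.08. Long non-coding RNAs gave 28 rises and 28 falls of 506 in MCF-7RR and 3 and 8 in MDA-MB-231RR, with median changes of 0.04 and -0.21. The class was not tested for enrichment, and labelling of short RNAs on these arrays was not examined.

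The 2 MCF-7RR arrays differed from each other at single genes. S100A8, a calcium-binding alarmin, stood at 10.52 in replicate 1 and 6.79 in replicate 2, against 10.52 on average in MCF-7. Of the 8 genes lowest in replicate 2 against replicate 1, the others (log2 differences) were STEAP4 -3.40, EHF -2.85, CCDC59 -2.76, LCN2 -2.65, S100A7 -2.41, IFIT1 -2.17 and SLITRK6 -2.13. The 8 genes highest in replicate 2 were TXNIP 3.39, SNORA38B 2.62, MMP16 2.49, NDST4 2.41, LINC00052 2.08, IFI44 1.77, ZNF204P 1.71 and NDRG1 1.60. The interferon list had a median of -0.12 in replicate 1 and -0.33 in replicate 2 against MCF-7. These are differences between 2 arrays with no test.

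Runs of neighbouring genes changed together in MCF-7RR, which as a hypothesis could come from a change in copy number. Among 14939 protein-coding genes in genome order, the 31-gene window with the highest median (0.57 over its genes from AK3 to RPS6, centred on MPDZ) had 27 genes above 0 and 14 called higher. The lowest window (median -0.49, from PLAA to MYORG, centred on B4GALT1) lay on the same chromosome and had 25 genes below 0 and 11 called lower. Less the median of all these genes, the highest window stood at 0.62, above the highest window of each of 1000 shuffles of gene order (at most 0.39; permutation test, p = 0.001, the smallest they can give). The lowest window, at -0.44, lay just beyond the lowest of the shuffles (-0.43). Shuffled gene order is not a clean reference, since differences between replicates of a group, with no change of phenotype, gave p = 0.05 for the highest window in MCF-7RR and p = 0.03 for the lowest in parental MDA-MB-231 by the same permutation test, with smaller windows (0.24 and -0.31). Both replicates showed the runs (medians 0.40 and 0.65, and -0.55 and -0.49), while MDA-MB-231RR had medians of 0.19 and -0.01 there. The windows were picked on the mean of these same MCF-7RR arrays. Agreement between the replicates, and the counts of genes within the windows, were thus partly built in. MDA-MB-231RR had windows of its own beyond the shuffles, the highest around RHOBTB3 and the lowest around the histone gene H2AC12. The correlation between adjacent genes was 0.20 in MDA-MB-231RR and 0.09 in MCF-7RR, so runs were not particular to MCF-7RR. Such runs can also come from neighbouring genes under common control, and DNA was not measured.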
